A study of Homo sapiens with 18 samples.

How the data were processed

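Gene expression was measured by sequencing of total RNA in 3 human cancer cell lines treated with vehicle or with 10 µM ST101, a peptide antagonist of the transcription factor C/EBPβ, for 24 h. The lines were A549, derived from a lung adenocarcinoma, MCF7, derived from an oestrogen receptor positive breast cancer, and U251, derived from a glioblastoma. The labels name 18 samples, 3 per line and treatment, and call them biological replicates. The deposited tables hold columns for 17 of these. The table for A549 has no column for ST101 replicate 3, which was therefore not analysed here. The design written before the data were examined assumed 18 libraries with 6 per line, and A549 was compared as 2 ST101 libraries with 3 vehicle libraries.

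According to the submitters' processing notes, base calls came from CASAVA and reads were aligned with STAR to GRCh38. The read counter, the annotation release, the strand of the library and the tool behind the deposited comparison are not given in the sources used here. Each deposited table holds read counts per gene and library, per the file headers. It also holds FPKM values computed by the authors. For each group the authors give a signal value, the mean of the counts after division by a size factor. The authors' comparison of ST101 with vehicle is deposited as a log2 fold change. The authors also give a p-value, with its adjusted form, for that comparison. The remaining deposited column used is gene length in bases, an other kind of value. The FPKM values and the group means were recomputed from the counts, with largest relative deviations of 1e-06 and 5e-10. All 39731 gene identifiers occur in GENCODE v29, 94.6% of them with the same coordinates, and chromosome positions below are those in the files. Because the strand is not known, genes that overlap another gene on the opposite strand, CEBPB among them, have uncertain counts.

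Only the read counts were analysed. They ranged from 28277691 to 39392421 per library. A count of 3 in a library, taken as its floor, corresponds to 0.076 to 0.106 CPM, counts scaled to the library total. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. The p-values measure the spread between replicates. Replicate pairs were compared gene by gene with the spread that counting alone would give. The chi-square per degree of freedom ranged from 2.93 to 22.55 over 16 pairs. It was 22.55 and 19.93 for A549 vehicle replicate 2 with replicates 1 and 3, against 4.16 between those. It was 22.33 and 20.66 for MCF7 ST101 replicate 3 with replicates 1 and 2, against 9.85 between those.

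Each line was fitted alone with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, robust quasi-likelihood fit, two-sided F-test). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a call is an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the F statistic. Differences in response between lines were tested as interaction contrasts in one edgeR fit of all 17 libraries over 19834 genes. CPM values are means ± SD over the libraries of a group, after TMM normalization. The mitochondrial share is the percentage of all counts on mitochondrially encoded genes.

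The groups of genes compared are 35 lists fixed before the data were examined, as were the tests of ST101 against vehicle, the filters and the alternatives. The tests and lists chosen later are named where they are used. Each list was tested in each line, where at least 5 members were measured, with camera from limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the lists of that line. Camera with an estimated correlation, camera on ranks and fry stand beside it. With an estimated correlation camera also tests on the residual degrees of freedom of the fit. These are few within a line and more in the fit of all 17 libraries. A call lost in that setting therefore need not mean that the genes of a list were correlated. Fry asks whether the genes of a list move one way on balance, without comparing them with other genes. The genes named were also chosen by a rule fixed in advance. It takes every measured C/EBP family member. It takes, per line, the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change. These had to be called, with a mean of at least 100 normalized counts and groups that did not overlap. It takes up to 4 members of each list with the smallest adjusted p. Across lines it takes up to 10 genes per direction called the same way in all 3 lines, and for each pair of lines 5 genes per direction with the largest difference in response, among genes with an adjusted p under 0.05 for the difference. Both of these parts also ask for a mean of at least 100 normalized counts in every line compared.

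The tests were tested on simulated data with 200 changed genes per line. Far more genes were called in the data of A549 (7633) and U251 (10646), so the rates below do not cover changes that wide. At 1.5-fold, edgeR recovered 74.6% of the changed genes in the A549 layout, 82.1% in MCF7 and 92.5% in U251. At 2-fold it recovered 97%, 98.5% and 98.5%, and false calls were 5.7%, 7.4% and 5.4% of calls. Of 200 random lists, camera at the preset correlation gave 14 an unadjusted p under 0.05. The simulated genes varied independently of each other, so this does not test camera on lists of correlated genes.

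Alternatives to the main choices were DESeq2 1.42.0, limma-voom, DESeq2's size factors, scaling by library total alone, no filter, a mean of at least 50 normalized counts, protein-coding genes alone, a replicate block, a fit that was not robust, one fit of all libraries, thresholds of 0.01 and of a 2-fold change, and leaving out each library in turn. An alternative pseudocount was not run, since the tests use the counts themselves. Splits of the libraries that mixed the groups were counted for the comparisons with 3 libraries in each group.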

Results

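RNA-seq read counts were available for 17 libraries. A549 had 3 vehicle and 2 ST101 libraries, and MCF7 and U251 each had 3 vehicle and 3 ST101 libraries. Total counts per library were 28277691 to 37594310 in A549, 31215280 to 39392421 in MCF7 and 29985512 to 39037455 in U251. Mitochondrially encoded genes took 5.58 ± 0.06% of counts (SD, n = 2) with ST101 in A549 and 3.17 ± 0.94% (SD, n = 3) with vehicle. The A549 vehicle libraries had shares of 3.86%, 2.1% and 3.56%. In MCF7 the shares were 4.46 ± 0.43% and 4.45 ± 0.35%, and in U251 3.72 ± 0.36% and 4.1 ± 0.38% (SD, n = 3 each). The 10 most abundant genes took 6.07 ± 0.1% of U251 counts with ST101 and 7.65 ± 0.11% with vehicle (SD, n = 3 each). For each line the question was which genes ST101 changed against vehicle after 24 h, and between lines whether those responses differed.

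CEBPB, which encodes the transcription factor that ST101 is directed against, changed little at the mRNA level. The gene (ENSG00000172216, chromosome 20, 50190734 to 50192689) overlaps an antisense gene, so its counts may include reads from that strand. In A549 CEBPB rose from 179 ± 3.88 CPM (SD, n = 3) to 204 ± 1.79 CPM (SD, n = 2), a log2 fold change of 0.19 ± 0.05 (SE; edgeR adjusted p = 0.0012). In MCF7 it was 174 ± 7.88 and 169 ± 5.61 CPM (SD, n = 3 each; edgeR adjusted p = 0.717). In U251 it rose from 79.6 ± 1.84 to 86.0 ± 3.46 CPM (SD, n = 3 each), by 0.11 ± 0.04 on the log2 scale (SE; edgeR adjusted p = 0.0167). The U251 call was lost without vehicle replicate 1 (edgeR adjusted p = 0.0536), without ST101 replicate 2 (0.12), with scaling by library total alone (0.366), in one fit of all libraries (0.14) and among protein-coding genes alone (0.052). The response of CEBPB was higher in A549 than in MCF7 by 0.21 (log2; edgeR adjusted p = 0.016), while the differences between A549 and U251 (0.09, adjusted p = 0.277) and between MCF7 and U251 (-0.12, adjusted p = 0.149) did not pass.

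CEBPD, a related family member induced in acute-phase responses, fell in A549 and in U251. It went from 108 ± 2.96 to 48.4 ± 0.927 CPM in A549 (SD, n = 3 and 2; log2 fold change -1.16, edgeR adjusted p = 3.84e-20) and from 110 ± 7.88 to 27.6 ± 0.948 CPM in U251 (SD, n = 3 each; -1.99, adjusted p = 2.35e-30). In MCF7 CEBPD was 19.8 ± 3.64 and 19.2 ± 2.35 CPM (SD, n = 3 each; edgeR adjusted p = 0.919), and its response differed from that in A549 (-1.14 for A549 minus MCF7) and in U251 (1.99 for MCF7 minus U251). CEBPA, which drives differentiation in several lineages, fell in U251 from 11.1 ± 1.51 to 1.65 ± 0.187 CPM (SD, n = 3 each; -2.76, edgeR adjusted p = 2.12e-21). CEBPG rose in U251 by 0.34 and DDIT3, a stress-induced member, by 0.54. In A549 CEBPZ fell by 0.44 on the log2 scale, CEBPA by 0.44 (edgeR adjusted p = 0.00373; 0.223 without ST101 replicate 2) and CEBPG by 0.13 (0.0224). The CEBPG call in A549 was lost without vehicle replicate 1 (edgeR adjusted p = 0.0619), ST101 replicate 1 (0.0851) and ST101 replicate 2 (0.154), with DESeq2 (0.0553), with a mean of at least 50 normalized counts (0.0597) and among protein-coding genes alone (0.052). Of the 6 measured members of the C/EBP family list, 1 rose and 4 fell in A549 (the same numbers when adjusted over the list alone), none was called in MCF7 by edgeR, and 3 rose and 2 fell in U251. The family list passed camera in A549 (adjusted p = 0.0174) but not with an estimated correlation (adjusted p = 0.224), and it did not pass in MCF7 (0.643) or U251 (0.0826).

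**Figure D1:**
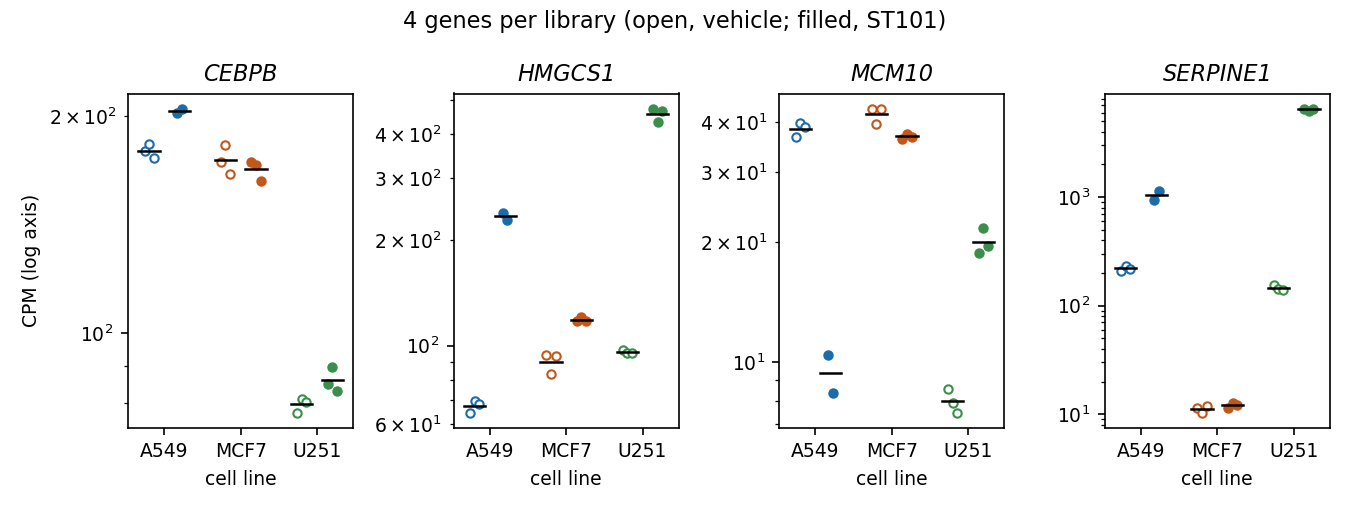
CPM on a log axis for CEBPB, HMGCS1, MCM10 and SERPINE1 in each library of A549, MCF7 and U251. Open points are vehicle libraries, filled points ST101 libraries and bars group means. SERPINE1 in U251 ran from 139 to 156 CPM with vehicle and from 6240 to 6520 CPM with ST101.

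In A549 genes for DNA replication and mitosis fell. MCM4 (ENSG00000104738, chromosome 8, 47960185 to 47978160), a subunit of the replicative helicase, fell from 234 ± 5.00 to 73.5 ± 6.73 CPM (SD, n = 3 and 2; log2 fold change -1.67 ± 0.05 SE, edgeR adjusted p = 2.2e-24). MCM5, another subunit, fell by 1.51 on the log2 scale and TK1, a thymidine kinase of S phase, by 1.40. All 35 measured members of the DNA replication list fell, with a median log2 fold change of -1.39 (35 of 35 also adjusted over the list alone). Of 35 members of the mitosis list 34 fell, among them AURKA, a spindle kinase, at -1.14 and BIRC5, which acts in chromosome segregation and in apoptosis, at -1.17. Of 11 cyclins and CDKs 10 fell, including CCNA2 at -1.33 and CDK1 at -1.19, while the remaining one, outside the rule for named genes and named after its values were seen, was CCND1, the cyclin of early G1, which rose by 0.34. Camera gave adjusted p = 9.72e-91, 6.87e-58 and 1.34e-13 for replication, mitosis and cyclins, and adjusted p = 0.0122, 0.0108 and 0.0266 with an estimated correlation. MCM10, a replication initiation factor and a member of the replication list, was at -2.03. Genes outside these lists included EXO1, a DNA repair exonuclease, at -2.03, E2F2 at -1.87 and E2F8 at -1.86. Adjusted over the list alone, the counts for mitosis and cyclins were also 34 and 10 lower.

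Genes of sterol and fatty acid synthesis rose in A549. HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512), an early enzyme of the mevalonate pathway, rose from 67.5 ± 2.63 to 233 ± 7.06 CPM (SD, n = 3 and 2; 1.79, edgeR adjusted p = 4.63e-27). MSMO1, a later sterol enzyme, rose from 46.4 ± 0.81 to 212 ± 0.262 CPM (2.19), and INSIG1, a sterol-regulated brake on the same pathway, rose by 1.73. SCD, which desaturates fatty acids, went from 1240 ± 11.4 to 3548 ± 37 CPM (1.52), and ACSS2, which makes acetyl-CoA, rose by 2.00. Of 25 cholesterol biosynthesis genes 24 rose (24 higher and 1 lower adjusted over the list alone; median 1.53; camera adjusted p = 2.84e-107, and 0.0122 with an estimated correlation). Of 15 fatty acid synthesis genes 13 rose and 1 fell (the same adjusted over the list alone; median 0.75; camera adjusted p = 1.03e-22, and 0.0143 with an estimated correlation).

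All 4 ID genes fell in A549, and SERPINE1, PMEPA1 and COL1A1 were among the genes that rose. SERPINE1 (ENSG00000106366, chromosome 7, 101127089 to 101139266), which encodes an inhibitor of plasminogen activation, rose from 221 ± 12.8 to 1043 ± 132 CPM (SD, n = 3 and 2; 2.24, edgeR adjusted p = 1.14e-11). PMEPA1, a feedback inhibitor of TGF-β signalling, rose by 2.32, COL1A1, a fibrillar collagen chain, by 2.49, LAMC2, a laminin chain, by 2.86 and the cytokine IL11 by 2.97. MAF, a transcription factor, rose from 0.825 ± 0.266 to 17.3 ± 3.66 CPM (4.36). ID4 fell from 15.1 ± 1.43 to 1.31 ± 0.191 CPM (-3.52), and ID2 from 142 ± 7.92 to 31.8 ± 0.649 CPM (-2.16); ID proteins bind and inhibit basic helix-loop-helix transcription factors. ID1 fell by 0.96 on the log2 scale and ID3 by 0.91, so all 4 members of the ID family fell (4 of 4 also adjusted over the list alone; too few for camera). Of 20 TGF-β and SMAD targets 12 rose and 7 fell, of 31 mesenchymal state genes 19 rose and 3 fell, and of 20 YAP and TAZ targets 3 rose and 13 fell. Adjusted over the list alone these counts were 12 and 7, 19 and 3, and 4 and 13. Camera adjusted p-values were 4.12e-05, 5.51e-10 and 1.56e-05, and 0.175, 0.166 and 0.087 with an estimated correlation. AMOTL2 and AJUBA, both linked to Hippo signalling, fell by 1.75 and 1.02 on the log2 scale. Among fibroblast and endothelial markers 3 of 6 rose, 1 of them the COL1A1 above (3 adjusted over the list alone; camera adjusted p = 0.000754, and 0.148 with an estimated correlation).

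Stress, apoptosis, cytokine and lysosome lists had members called in both directions in A549. Of 26 p53 targets 13 rose and 3 fell, CDKN1A, a CDK inhibitor, by 0.94 and TP53INP1 by 1.09 among the higher ones. Of 18 pro-apoptotic genes 8 rose and 3 fell, with BMF at 1.51, and of 11 anti-apoptotic genes 3 rose and 3 fell, with MCL1 at 0.72 and BCL2L1 at -0.36. NF-κB and cytokine genes rose in 12 and fell in 4 of 24 cases, including CXCL8, a neutrophil attractant, at 1.10 and NFKB2 at 0.89. Lysosome and autophagy genes rose in 18 and fell in 2 of 34, with the cholesterol exporter NPC1 at 0.99. Camera adjusted p-values for the p53, pro-apoptotic, NF-κB and lysosome lists were 2.4e-05, 0.0116, 0.000168 and 4.69e-05, and 0.121, 0.175, 0.199 and 0.199 with an estimated correlation. All of these counts were the same adjusted over the list alone. The anti-apoptotic list did not pass camera (adjusted p = 0.812), and its median of 0.09 differed in sign from its mean of -0.07 and from the direction of the test.

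Several other A549 lists had more members lower than higher. NRF2 targets fell in 19 of 25 cases with 1 higher, including GCLC, which makes glutathione, at -0.71. ATF4 targets fell in 18 and rose in 6 of 34, with PSAT1, a serine synthesis enzyme, at -0.73. MYC and nucleolar genes fell in 26 of 34, with NOLC1 at -0.57, and literature C/EBPβ targets fell in 9 and rose in 5 of 19. The C/EBPβ targets that fell include ID1, ID2, ID3, CCNA2 and CEBPD, and those that rose include CCND1 and CXCL8. All of these are given above, so this list is not separate from them. Fibrinogen chains FGA and FGB fell by 0.90 and 1.02 on the log2 scale, and all 10 A549 markers fell (median -0.58). AKR1B10, AKR1C1, AKR1C2 and AKR1C3 belong to both the A549 marker list and the NRF2 list. Hypoxia and glycolysis genes fell in 20 and rose in 5 of 32, with BNIP3 at -0.56. Camera adjusted p-values for these 6 lists were 2.37e-06, 0.0116, 1.11e-07, 0.00255, 5.51e-10 and 0.00414, and 0.322, 0.345, 0.24, 0.175, 0.186 and 0.51 with an estimated correlation. The hypoxia call was also lost without ST101 replicate 1 (camera adjusted p = 0.0651). Adjusted over the list alone, 20, 18, 27, 9, 10 and 23 members of these lists were lower.

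Respiratory and ribosomal genes stand beside the mitochondrial share of the A549 libraries given above. Of 41 nuclear-encoded oxidative phosphorylation genes 35 were lower in A549 (36 adjusted over the list alone), with ATP5G1 at -0.50, and of 67 cytosolic ribosomal protein genes 61 were lower (65 lower and 1 higher adjusted over the list alone; median -0.23). None of the 13 mitochondrially encoded mRNAs was called by edgeR, with a median log2 fold change of 0.79. The 3 lists passed camera (adjusted p = 3.34e-06, 1.54e-06 and 0.000754), and not with an estimated correlation (adjusted p = 0.33, 0.472 and 0.472). Without vehicle replicate 2, whose mitochondrial share was 2.1%, 9 of the 13 mitochondrial mRNAs were higher (median 0.57) and 60 of the ribosomal protein genes were lower (median -0.18).

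The remaining A549 lists did not pass camera. ER chaperones rose in 11 and fell in 1 of 21 cases (adjusted p = 0.0666), with EDEM1 at 0.68 and XBP1 at -0.74. Heat shock genes fell in 9 and rose in 2 of 18 (0.0573), metallothionein and zinc genes rose in 4 and fell in 1 of 6 (0.0558), and interferon response genes rose in 7 and fell in 3 of 30 (0.42). Immediate early genes rose in 7 and fell in 6 of 27 (0.885), with FOS at -0.89 and JUNB at 0.65. Epithelial junction genes rose in 3 and fell in 9 of 19 (0.904), with CLDN4 at 1.68 and CDH1 at -0.59. For these last lists, the medians of -0.12 and -0.19 were negative and the test direction positive. Oestrogen receptor targets rose in 7 and fell in 11 of 24 (0.637), MCF7 markers in 3 and 3 of 8 (0.351) and U251 markers in 1 and 1 of 5 (0.826). None of 4 measured haematopoietic markers was called by edgeR. Adjusted over the list alone, the heat shock and oestrogen lists had 10 and 12 members lower, the interferon list 2 lower and the U251 markers 2 higher.

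In total edgeR called 7633 of 17353 genes in A549, 3663 higher and 3970 lower, and 1321 of these changed at least 2-fold, 942 higher and 379 lower. The median absolute log2 fold change of the called genes was 0.40. In 7584 of the called genes the ST101 libraries lay on one side of the vehicle libraries, as they did in 64% of all genes tested, where regrouping at random gives 20% for 3 against 2. The authors' deposited comparison lists 6020 genes with an adjusted p under 0.05, 5912 of which were among these calls.

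**Figure D2:**
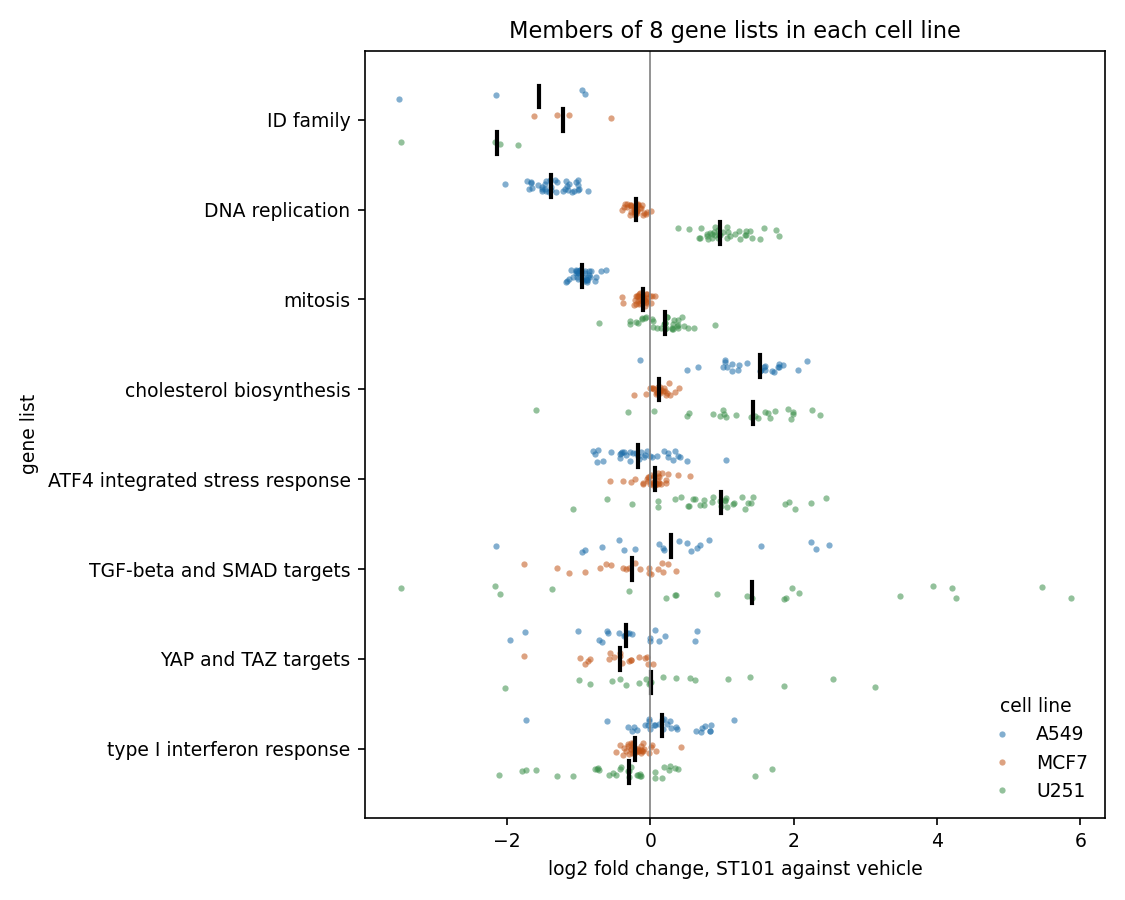
Log2 fold change with ST101 against vehicle for each measured member of 8 gene lists in A549, MCF7 and U251. Each point is a gene and each black bar the median of a list. The medians of the DNA replication list were -1.39 in A549, -0.2 in MCF7 and 0.96 in U251.

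In MCF7 the changes were few and small, and the ID genes were again lower. ID1 fell from 120 ± 8.58 to 48.6 ± 4.94 CPM (SD, n = 3 each; log2 fold change -1.30, edgeR adjusted p = 8.48e-06) and ID2 from 51.1 ± 4.12 to 23.2 ± 2.58 CPM (-1.14, adjusted p = 1.12e-05). ID4 fell by 1.62 and ID3 by 0.55 on the log2 scale (4 of 4 also adjusted over the list alone). AQP3, a water and glycerol channel, rose from 207 ± 10.2 to 328 ± 3.34 CPM (0.66, edgeR adjusted p = 6.29e-06). NAV2 rose by 0.64, the bradykinin receptor gene BDKRB2 by 0.84, the adaptor gene SHC4 by 0.79 and NPR1, a natriuretic peptide receptor, by 0.71. PGM5 fell from 9.31 ± 0.961 to 3.93 ± 0.717 CPM (-1.24), FOXI1, a forkhead factor, by 1.03, PSG9 by 0.99 and GABRP, a GABA receptor subunit, by 0.94 on the log2 scale.

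Of the DNA replication genes 17 fell in MCF7, by small amounts. DHFR, which regenerates tetrahydrofolate, fell from 96.5 ± 1.65 to 74.8 ± 0.75 CPM (SD, n = 3 each; -0.37, edgeR adjusted p = 0.000295). TK1 fell by 0.33, CDC45, a helicase subunit, by 0.33 and RRM2, a ribonucleotide reductase subunit, by 0.28 on the log2 scale. Of the 35 measured none rose (26 lower adjusted over the list alone; median -0.20; camera adjusted p = 4.81e-25, and 0.0474 with an estimated correlation). Of 35 mitosis genes 1 fell, and 9 adjusted over the list alone (median -0.11), and of 12 cyclins and CDKs 1 fell, and 5 adjusted over the list alone. Camera gave adjusted p = 5.16e-07 and 0.00138, and 0.231 and 0.166 with an estimated correlation.

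YAP and TAZ targets and sterol genes also had several members called in MCF7. AMOTL2 fell from 170 ± 3.61 to 114 ± 4.04 CPM (SD, n = 3 each; -0.57, edgeR adjusted p = 8.48e-06), NT5E, an enzyme that makes adenosine, by 0.57 and AJUBA by 0.51 on the log2 scale. Of 19 YAP and TAZ targets 6 fell and none rose (14 lower adjusted over the list alone; median -0.43; camera adjusted p = 1.29e-27, and 0.0943 with an estimated correlation). HMGCS1 rose from 90.1 ± 6.25 to 118.5 ± 1.9 CPM (0.39, edgeR adjusted p = 0.000957), MSMO1 by 0.35 and SQLE, which oxidizes squalene, by 0.27. Of 24 cholesterol genes 6 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.12; camera adjusted p = 1.71e-08, and 0.196 with an estimated correlation). None of 15 fatty acid genes was called by edgeR, and 10 were higher adjusted over the list alone (camera adjusted p = 8.83e-06, and 0.196 with an estimated correlation).

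Of 20 TGF-β and SMAD targets 2 rose and 5 fell in MCF7 (4 and 9 adjusted over the list alone; camera adjusted p = 1.54e-13, and 0.149 with an estimated correlation). The ID genes were 3 of the members that fell, and FN1, the fibronectin gene, rose by 0.36. Literature C/EBPβ targets, which hold the same 3 ID genes, fell in 4 of 14 cases (2 higher and 4 lower adjusted over the list alone). Their median of 0.01 was positive and their mean of -0.08 and test direction negative (camera adjusted p = 1.48e-06, and 0.0849 with an estimated correlation). Immediate early genes rose in 1 and fell in 6 of 27 (5 and 7 adjusted over the list alone), with DUSP4, a MAP kinase phosphatase, at 0.32 (camera adjusted p = 2.25e-05, and 0.349 with an estimated correlation). MCF7 markers rose in 2 of 10 cases (4 adjusted over the list alone; 0.00166, and 0.149 with an estimated correlation). ER chaperones rose in 2 of 21 (2 adjusted over the list alone; 0.00182, and adjusted p = 0.231 with an estimated correlation). None of 34 lysosome genes was called by edgeR (camera adjusted p = 0.00429, and 0.231 with an estimated correlation).

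Further MCF7 list calls depended on single libraries. For p53 targets 1 of 26 rose (camera adjusted p = 0.018; 0.0684 without vehicle replicate 2 and 0.429 without ST101 replicate 3). For interferon genes 1 of 35 rose although the median was -0.21 and the test direction negative (0.000885; 0.0685 without vehicle replicate 2 and 0.701, in the other direction, without ST101 replicate 3). For NRF2 targets 1 of 25 rose (0.0298; 0.066 without vehicle replicate 2, 0.0611 without vehicle replicate 3 and 0.0789 without ST101 replicate 3). Metallothionein and zinc genes rose in 1 and fell in 1 of 5 cases (0.0318; 0.1 without ST101 replicate 3), and mesenchymal genes rose in 3 of 27 (0.00767; 0.0684 without vehicle replicate 2). None of 41 oxidative phosphorylation genes was called by edgeR (camera adjusted p = 0.000885; 0.276 without ST101 replicate 2), nor any of 67 ribosomal protein genes (2.04e-05; 0.732 without ST101 replicate 2). Of 34 MYC and nucleolar genes 1 rose, with a median of -0.06 (0.0346; 0.0685 without vehicle replicate 2 and 0.117 without ST101 replicate 3). With an estimated correlation the adjusted p-values of these 8 lists were 0.632, 0.64, 0.196, 0.214, 0.304, 0.64, 0.64 and 0.208. Adjusted over the list alone, 3, 1, 7, 1, 7, 0, 0 and 1 members were higher and 2, 0, 1, 2, 2, 0, 0 and 0 lower.

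The other MCF7 lists did not pass camera. NF-κB genes fell in 1 of 15 cases, NFKBIA at -0.33 (adjusted p = 0.143), and ATF4 targets rose in 1 and fell in 2 of 34 (0.232). Pro-apoptotic genes had no call among 18 by edgeR (0.614), and anti-apoptotic genes 1 lower of 10 (0.666). Heat shock genes fell in 1 of 17 (0.575), epithelial junction genes rose in 1 of 23 (0.833), hypoxia genes rose in 1 and fell in 2 of 32 (0.723) and oestrogen receptor targets rose in 3 and fell in 2 of 27 (0.143). None of 13 mitochondrially encoded mRNAs (0.0683) or 7 A549 markers (0.848) was called by edgeR. The same held for 4 U251, 4 haematopoietic and 3 fibroblast and endothelial markers, too few for camera. Adjusted over the list alone, the largest counts among these lists were 4 higher among oestrogen receptor targets, 4 lower among hypoxia genes and 3 in either direction among ATF4 targets.

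In total edgeR called 436 of 17375 genes in MCF7, 210 higher and 226 lower, 27 of them by at least 2-fold, 4 higher and 23 lower. With scaling by library total alone the directions were 252 higher and 196 lower. The median absolute log2 fold change of the called genes was 0.31. Without adjustment 2790 genes had p under 0.05. Of the 70 called genes that the naming rule gives in MCF7, 28 kept the call in each alternative run and without each library, and the MCF7 genes named as changed here are among these. The count moved with each library left out. It was 233, 81 and 107 without vehicle replicates 1, 2 and 3, and 703, 185 and 825 without ST101 replicates 1, 2 and 3. In all 436 the groups did not overlap, as in 21.4% of all genes tested, where regrouping at random gives 10% for 3 against 3. The authors' deposited comparison lists 582 genes, 422 of them among these calls.

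In U251 the genes with the largest changes included SERPINE1, collagen and cytokine genes, which rose. GFAP and all 4 ID genes fell. SERPINE1 rose from 146 ± 8.72 to 6413 ± 151 CPM (SD, n = 3 each; log2 fold change 5.46 ± 0.05 SE, edgeR adjusted p = 3.42e-45). COL1A1 rose from 4.23 ± 0.247 to 249 ± 23.4 CPM (5.87), IL11 from 8.83 ± 0.283 to 299.7 ± 31.2 CPM (5.09) and LIF, a cytokine of the same family, from 15.1 ± 0.123 to 353 ± 8.88 CPM (4.55). GFAP, the intermediate filament of astrocytes, fell from 17160 ± 616 to 731 ± 13.7 CPM (-4.55, edgeR adjusted p = 5.84e-44). ID2 fell from 208 ± 9.61 to 18.6 ± 0.164 CPM (-3.48), and ID1, ID3 and ID4 fell by 2.17, 2.11 and 1.85 on the log2 scale (4 of 4 also adjusted over the list alone). ATOH8, a basic helix-loop-helix factor, fell by 5.90, PCK1, an enzyme of gluconeogenesis, by 5.22 and the potassium channel gene KCNB1 by 4.61. MFAP2 and FOXS1, whose vehicle values of 0.0371 and 0.0176 CPM lay under the floor, reached 16.9 ± 0.497 and 6.04 ± 0.984 CPM with ST101.

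**Figure D3:**
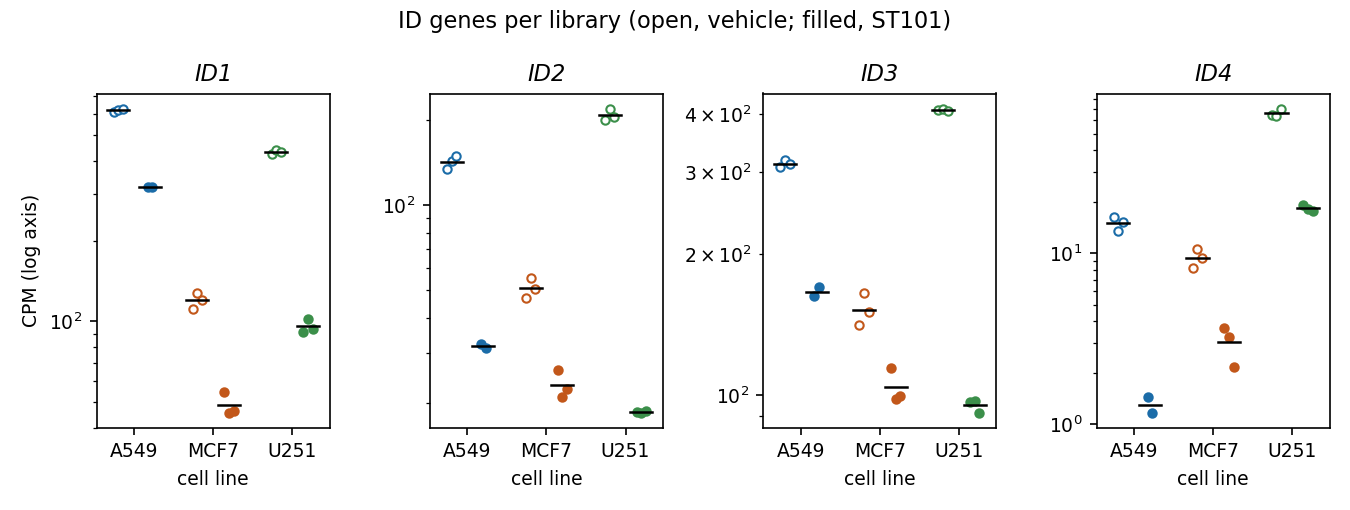
CPM on a log axis for ID1, ID2, ID3 and ID4 in each library of A549, MCF7 and U251. Open points are vehicle libraries, filled points ST101 libraries and bars group means. ID2 ran from 200 to 219 CPM with vehicle and from 18.5 to 18.8 CPM with ST101 in U251.

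TGF-β and SMAD targets rose in 16 and fell in 5 of 21 cases in U251 (the same adjusted over the list alone; median 1.41; camera adjusted p = 2.3e-14, and 0.0161 with an estimated correlation). PMEPA1 rose from 163 ± 5.19 to 1821 ± 44.5 CPM (SD, n = 3 each; 3.48), and the ID genes were 3 of the members that fell. Mesenchymal state genes rose in 21 and fell in 11 of 34 (the same adjusted over the list alone; 4.43e-11, and adjusted p = 0.06 with an estimated correlation), with the collagen gene COL6A3 at 3.09, TGFBI at 2.08 and the protease gene MMP2 at 1.76. NF-κB and cytokine genes rose in 16 and fell in 5 of 23 (the same adjusted over the list alone; 4.74e-05, and adjusted p = 0.0748 with an estimated correlation), with CSF1, a macrophage growth factor, at -1.98. Immediate early genes rose in 17 and fell in 3 of 26 (the same adjusted over the list alone; 0.000609, and adjusted p = 0.125 with an estimated correlation), with DUSP4 at 2.22 and DUSP6 at 1.83. YAP and TAZ targets rose in 9 and fell in 7 of 20 (the same adjusted over the list alone), NT5E at 3.14 and AMOTL2 at -2.04 among them. Their camera adjusted p was 0.0498, and 0.196 with an estimated correlation, 0.0688 without vehicle replicate 1 and 0.05 without vehicle replicate 3.

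Most members of the replication, ATF4 and cholesterol lists rose in U251. E2F1, a transcription factor of S-phase entry, rose from 30.7 ± 2.42 to 106 ± 3.6 CPM (SD, n = 3 each; 1.79, edgeR adjusted p = 3.04e-29), MCM4 from 147 ± 4.13 to 282 ± 3.28 CPM (0.94) and CCND1 from 53.1 ± 2.19 to 314 ± 28 CPM (2.57). All 35 replication genes rose (35 adjusted over the list alone; median 0.96; camera adjusted p = 1.13e-23, and 0.0784 with an estimated correlation). Cyclins and CDKs rose in 7 and fell in 2 of 11 (8 and 2 adjusted over the list alone; 0.00333, and adjusted p = 0.229 with an estimated correlation). Mitosis genes rose in 20 and fell in 5 of 35 (the same adjusted over the list alone) and did not pass camera (adjusted p = 0.224). PSAT1 and PHGDH, enzymes of serine synthesis, rose by 2.02 and 1.87, the folate enzyme gene MTHFD2 by 2.25 and the tRNA synthetase gene GARS by 1.32. ATF4 targets rose in 30 and fell in 3 of 34 (the same adjusted over the list alone; median 0.98; camera adjusted p = 2.5e-22, and 0.0108 with an estimated correlation). HMGCS1 rose from 95.9 ± 1.05 to 456.5 ± 20.3 CPM (2.25), SQLE by 1.99 and INSIG1 by 1.97. Cholesterol genes rose in 21 and fell in 2 of 24 (the same adjusted over the list alone; median 1.43; camera adjusted p = 1.53e-35, and 0.0479 with an estimated correlation).

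Fatty acid synthesis genes rose in 10 and fell in 4 of 15 in U251, with FADS2, a desaturase, at 1.47. ER chaperones rose in 18 of 21 (20 adjusted over the list alone), with MANF at 1.22 and HSPA5, the chaperone BiP, at 0.76. MYC and nucleolar genes rose in 25 and fell in 1 of 34, with SRM, a polyamine enzyme, at 0.86. p53 targets rose in 11 and fell in 7 of 25, with GDF15, a stress-induced cytokine, at 2.47 and CDKN1A at 1.51. Oestrogen receptor targets rose in 7 and fell in 6 of 17, with the corepressor gene NRIP1 at 1.82. Camera adjusted p-values for these 5 lists were 3.59e-06, 1.17e-05, 0.00924, 0.0242 and 0.0284, and 0.161, 0.0552, 0.418, 0.229 and 0.164 with an estimated correlation. Except for ER chaperones, the counts were the same adjusted over the list alone.

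In U251 the interferon, lysosome, metallothionein and NRF2 lists had more members lower than higher. PARP9 and DTX3L, partners in interferon signalling, fell from 159 ± 1.83 to 36.9 ± 2.67 CPM and from 149.6 ± 4.01 to 49.3 ± 1.14 CPM (SD, n = 3 each; -2.11 and -1.60). Interferon genes fell in 20 and rose in 5 of 34 (camera adjusted p = 0.000966, and 0.258 with an estimated correlation). Lysosome and autophagy genes fell in 22 and rose in 7 of 34, with GPNMB, a lysosomal glycoprotein, at -2.13 and NPC2, a sterol carrier, at 1.48 (camera adjusted p = 0.00171, and 0.354 with an estimated correlation). Metallothionein and zinc genes fell in 4 and rose in 1 of 6, with MT1E at -1.80 (0.00185, and adjusted p = 0.229 with an estimated correlation). NRF2 targets fell in 15 and rose in 7 of 25, with AKR1C1 at -2.10 and GCLM, a glutathione synthesis gene, at 1.57. Their camera adjusted p was 0.0449, and 0.418 with an estimated correlation, 0.0764 without ST101 replicate 1 and 0.078 without ST101 replicate 3. These counts were the same adjusted over the list alone.

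U251 markers rose in 5 and fell in 5 of 10 cases, S100B, an astrocytic calcium-binding protein, at -2.31 and FABP7, a fatty acid carrier of neural progenitors, at 0.87. Their median of 0.15 was positive, and their mean of -0.43 and test direction were negative (camera adjusted p = 0.00537, and 0.125 with an estimated correlation). A549 markers, which share their AKR genes with the NRF2 list, fell in 4 and rose in 1 of 6 (0.00434, and adjusted p = 0.157 with an estimated correlation). MCF7 markers rose in 2 and fell in 1 of 5 (0.303). Among fibroblast and endothelial markers 3 rose, COL1A1, PDGFRB at 1.77 and KDR at 1.2, and 3 fell, with PDGFRA at -1.65, of 7 measured (0.136; median -0.07 and mean 0.61). Of 3 haematopoietic markers 1 rose, CSF1R, a macrophage receptor gene, from 1.04 ± 0.195 to 7.28 ± 0.59 CPM (SD, n = 3 each; 2.81). These counts were the same adjusted over the list alone.

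Other U251 lists did not pass camera. Literature C/EBPβ targets rose in 10 and fell in 7 of 20 (11 and 7 adjusted over the list alone; adjusted p = 0.329), with TNFAIP6, a matrix-binding protein of inflammation, from 0.367 ± 0.048 to 15.8 ± 0.657 CPM (5.42). Their median of 0.23 and mean of 0.57 were positive and the test direction negative. Those that fell include ID1, ID2, ID3 and CEBPD, and those that rose include CCND1, all given above. The C/EBP family had a median of 0.09 and a mean of -0.62. Pro-apoptotic genes rose in 8 and fell in 4 of 16 (0.792), with PMAIP1 at 1.18 and BMF at -1.22, and anti-apoptotic genes rose in 3 and fell in 4 of 10 (0.792; median 0.01, mean -0.08). Hypoxia genes rose in 17 and fell in 9 of 32 (0.182), with the glucose transporter gene SLC2A1 at 0.85, and heat shock genes rose in 10 and fell in 3 of 18 (0.154; 11 and 3 adjusted over the list alone). Ribosomal protein genes rose in 36 and fell in 6 of 67 (0.329), oxidative phosphorylation genes rose in 8 and fell in 23 of 41 (0.207), and 1 of 13 mitochondrially encoded mRNAs was lower (0.832; median 0.02, mean -0.01). Epithelial junction genes rose in 5 and fell in 4 of 14 (0.971), with a median of -0.01, a mean of -0.09 and a positive test direction.

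In total edgeR called 10646 of 16971 genes in U251, 5387 higher and 5259 lower, 2231 of them by at least 2-fold, 1099 higher and 1132 lower. The balance of directions depended on the scaling, with 4560 higher and 6232 lower when scaled by library total alone. The median absolute log2 fold change of the called genes was 0.47. In 10139 of them the groups did not overlap, as in 65.7% of all genes tested, where regrouping at random gives 10% for 3 against 3. The authors' deposited comparison lists 9300 genes, 9067 of them among these calls.

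All 35 replication genes fell in A549 and all rose in U251. In MCF7 17 fell and 18 were not called (median -0.20). All 35 were more negative in A549 than in U251 (median difference -2.28; camera adjusted p = 6.11e-138, and 2.73e-06 with an estimated correlation), in A549 than in MCF7 (-1.14; 2.63e-101, and adjusted p = 5.16e-06 with an estimated correlation) and in MCF7 than in U251 (-1.15; 1.09e-59, and adjusted p = 0.000204 with an estimated correlation). ATF4 targets were more negative in A549 and in MCF7 than in U251 (-0.89 and -0.82; camera adjusted p = 2.65e-25 and 1.44e-21, and 0.00116 and 0.00187 with an estimated correlation). Cholesterol genes responded more strongly in A549 and in U251 than in MCF7 (1.26 for A549 minus MCF7 and -1.25 for MCF7 minus U251; camera adjusted p = 5.13e-105 and 8.34e-38, and 2.72e-06 and 0.000204 with an estimated correlation), and the difference between A549 and U251 did not pass (0.09; 0.129). TGF-β targets were more positive in A549 than in MCF7 (0.57; 2.61e-14, and adjusted p = 0.00824 with an estimated correlation) and more negative in MCF7 than in U251 (-1.40; 2.16e-25, and adjusted p = 0.00165 with an estimated correlation). For A549 minus U251 their median difference was -1.15 (camera adjusted p = 5.57e-06, and 0.127 with an estimated correlation). At the level of genes, SERPINE1 differed by -5.32 and IL11 by -4.92 between MCF7 and U251, and NOTCH3 by -4.54 and the repressor gene E2F7 by -4.30 between A549 and U251. MAF responded more in A549 than in MCF7 (3.86) and U251 (4.16). By edgeR, responses differed for 4731 of 19834 genes between A549 and MCF7, for 8826 between A549 and U251 and for 7182 between MCF7 and U251.

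Genes that changed the same way in all 3 lines included the 4 ID genes, which fell, and HMGCS1 and MSMO1, which rose. DUSP4 also rose in every line, by 0.55 in A549, 0.32 in MCF7 and 2.22 in U251, and AMOTL2, AJUBA, NFKBIA, an inhibitor of NF-κB, and TNS3, a focal adhesion protein, fell in every line. TNS3 fell by 0.52 in A549, 0.80 in MCF7 and 0.54 in U251 on the log2 scale. In the separate edgeR fits 55 genes were higher in all 3 lines, against 13.1 for independent lists, and 27 were lower, against 14.4, of 14029 genes tested in all. The sum of 82 moved with the MCF7 libraries left out: it was 44, 22 and 23 without vehicle replicates 1, 2 and 3, and 132, 39 and 165 without ST101 replicates 1, 2 and 3. Between A549 and U251, 1190 genes were higher in both (1021.1 for independent lists), 901 lower in both (1113.2), and 1680 lower in A549 and higher in U251 (1208.5). Between A549 and MCF7, 98 were higher in both (38.7) and 111 lower in both (46.4), and between MCF7 and U251, 84 were higher in both (60.9), 53 lower in both (56.7) and 101 lower in MCF7 and higher in U251 (61.6). Across genes, which are not independent replicates, Spearman's rho of the log2 fold changes was 0.28 for A549 and MCF7, -0.07 for A549 and U251 and 0.03 for MCF7 and U251.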

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

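The counts, lists and genes in the next paragraphs were picked out because the response to ST101 differed between 2 cell lines in a test of the difference itself. The regroupings within a line and the A549 mitochondrial pattern further on are not such differences. The label swap test, the U251 marker test and the mitochondrial test without vehicle replicate 2 were chosen only after the results they address were seen. The responses of 4731 genes differed between A549 and MCF7, of 8826 between A549 and U251 and of 7182 between MCF7 and U251 (edgeR, adjusted p under 0.05).

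For A549 minus MCF7, the median differences of the lists that passed camera under both correlations were -1.14 for DNA replication, -0.85 for mitosis, -0.70 for cyclins and CDKs, -0.32 for NRF2 targets and -0.32 for MYC and nucleolar genes. They were 1.26 for cholesterol biosynthesis, 0.71 for fatty acid synthesis, 0.62 for NF-κB and cytokine genes, 0.57 for TGF-β and SMAD targets, 0.46 for metallothionein and zinc genes and 0.38 for mesenchymal genes. For A549 minus U251 they were -2.28 for DNA replication, -1.60 for cyclins and CDKs, -1.18 for mitosis, -0.89 for ATF4 targets and -0.51 for MYC and nucleolar genes. For MCF7 minus U251 they were -1.40 for TGF-β and SMAD targets, -1.25 for cholesterol biosynthesis, -1.15 for DNA replication, -0.82 for ATF4 targets, -0.42 for cyclins and CDKs and -0.30 for mesenchymal genes.

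Genes were taken here from those with an adjusted p under 0.05 for the difference (edgeR) and a mean of at least 100 normalized counts in both lines. Less abundant genes, some with larger differences, are left out. Among these, the largest differences for A549 minus MCF7 were MAF 3.86, IL11 2.82, PLEK2 2.77, COL5A1 2.64 and PCDH1 2.64 on the positive side. On the negative side they were ID4 -1.92, MCM10 -1.86, EXO1 -1.81, AUNIP -1.65 and E2F8 -1.64. For A549 minus U251 the differences were ATOH8 4.40, MAF 4.16, THSD7A 3.96, FAM167A 3.88 and PKD1L2 3.85, and BTBD11 -5.02, NOTCH3 -4.54, ANKRD1 -4.49, E2F7 -4.30 and LIF -3.72. For MCF7 minus U251 they were GLDN 3.10, PKD1L2 2.91, PARP14 2.82, KCP 2.79 and NTN4 2.75, and COL1A1 -5.66, SERPINE1 -5.32, BTBD11 -4.99 and IL11 -4.92. MFAP2, whose U251 vehicle value lay under the floor, also differed between MCF7 and U251 and is given no fold.

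Regrouping of the libraries was tried where the layout allowed it. For MCF7, 1 of 10 splits of the libraries into 3 and 3 called as many genes as the real one (436 against a highest other value of 0), and for U251 1 of 10 (10646 against 0), which are too few splits. For the difference between MCF7 and U251, 1 of 100 splits drawn from 200 called as many genes as the real one (7182), and the highest other value was 6937, from a split that kept the U251 groups. Among splits that regrouped U251 the highest value was 1.

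Of 35 DNA replication genes all fell in A549, 17 fell in MCF7 (median -0.20) and all rose in U251, where the list call was lost with an estimated correlation (limma camera, adjusted p = 0.0784). A trend of the fold changes with GC content, length and level could give such shifts, but the median residual after removing it was -1.32 in A549 and 0.96 in U251, so that trend is unlikely to be the whole cause. A swap of vehicle and ST101 labels in the U251 libraries could also reverse a shared response. Of the 162 genes outside the replication, mitosis and cyclin lists that were called the same way in A549 and MCF7 and also called in U251, 50.6% (95% interval 42.7% to 58.6%) went the same way in U251, which leaves that explanation undecided. That interval treats genes of the same libraries as independent, so it is too narrow. Cell cycle genes outside those lists were not removed. The 4 ID genes, lower in all 3 lines, ran against a swap. So did the cholesterol list, higher in 21 of 24 cases in U251 (median 1.43) and in 24 of 25 in A549 (1.53). In MCF7 6 of its 24 members rose and 1 fell (0.12). The ID genes, HMGCS1 and MSMO1 are among the 162 genes. They and the list were singled out after their values were seen, so they do not decide the question. A biological difference between the lines may account for the pattern.

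In U251 the ID genes fell while SERPINE1, PMEPA1 and COL1A1 rose steeply. Replacement of U251 cells in the ST101 cultures by cells without U251 markers could produce both, but it would lower all U251 markers, and 5 of 10 rose while 5 fell, with GFAP at -4.55 and S100B at -2.31. The markers had a median of 0.15 and a mean of -0.43 (SE of the mean over genes 0.57). The ID family had a median of -2.14 and a mean of -2.4 (SE of the mean over genes 0.37). These values argue against replacement by cells that lack all these markers as the whole cause. Partial replacement, or replacement by cells that express some of them, was not tested. Camera gave the marker list a negative direction (adjusted p = 0.00537). A trend with GC content, length and level left a median absolute residual of 3.39 for these 7 genes and may explain little of the pattern. A change in signalling upstream of these genes stays open, and targets of 2 such pathways are given under the other observations.

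In A549 the median log2 fold change was 0.79 for 13 mitochondrially encoded mRNAs, none of them called, and -0.23 for 67 ribosomal protein mRNAs, and both list calls were lost with an estimated correlation (limma camera, adjusted p = 0.472 for each). Vehicle replicate 2 has the lowest mitochondrial share and could cause this alone. Without it the respective medians were 0.57 and -0.18, which argues against that library as the sole cause. A difference in RNA quality or extraction between the A549 groups could also act on both lists and stays open.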

How the results depend on the processing

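Of the named genes called by edgeR, 140 of 151 in A549, 28 of 70 in MCF7 and 153 of 158 in U251 kept their call under each alternative that was run for them and gave a value, and without each library in turn, as did 30 of 30 differences between lines. The rule took those 30 from the largest differences called among well-counted genes, so they say little about the other differences called. Of the list calls by camera, 5 of 23 in A549, 1 of 20 in MCF7 and 3 of 20 in U251 did so, and 11 of 22, 5 of 17 and 5 of 19 for A549 minus MCF7, A549 minus U251 and MCF7 minus U251. The setting with an estimated correlation, which also has fewer degrees of freedom, ended most of the others. It also ended calls of lists with an estimate under the preset 0.01, such as YAP and TAZ targets in A549 (-0.031) and literature C/EBPβ targets in MCF7 (-0.017). DESeq2 called 6277, 589 and 9758 genes in A549, MCF7 and U251, and limma-voom 7602, 398 and 10641. In MCF7 the count of 436 became 1078 with no filter and 946 in one fit of all libraries, and the count of 82 in all 3 lines became 181 and 189; the cause was not tested. Stricter thresholds left fewer genes by construction: 132 in MCF7 and 22 in all 3 lines at an adjusted p under 0.01, and 1321 in A549, 27 in MCF7, 2231 in U251 and 6 in all 3 lines with a 2-fold change. Leaving out each library in turn gave 5412 to 7748 genes in A549, 81 to 825 in MCF7, 9883 to 10503 in U251 and 22 to 165 in all 3 lines. For differences it gave 3323 to 4641 (A549 and MCF7), 7672 to 9159 (A549 and U251) and 6550 to 7485 (MCF7 and U251). Fewer libraries lower the power, and the cause of the rises was not tested. Without 1 A549 ST101 library the other is assumed to vary like the rest. The MCF7 list type I interferon response changed direction without ST101 replicate 3 (camera adjusted p = 0.701) and ranged down to 2.15e-11 without ST101 replicate 1. The fibroblast and endothelial markers changed direction for MCF7 minus U251 with limma-voom (0.983) and with camera on ranks (0.683); the cause was not tested. With a replicate block the counts were 6748, 296 and 10478 in A549, MCF7 and U251, 54 in all 3 lines (the cause was not tested) and 4033, 8091 and 6656 for the 3 differences. Libraries with the same number correlated at -0.31 to -0.01 in their deviations, so the numbers were not taken to pair them. In MCF7, ST101 and vehicle libraries with different numbers correlated at -0.26 to 0.33. A factor shared across the MCF7 groups was not modelled or tested. The stricter thresholds were applied to the counts alone, protein-coding genes alone to genes within a line and their counts, and one fit of all libraries to none of the lists. An alternative pseudocount was not run. The tests use the counts themselves, but edgeR adds a small prior count by default when it computes log2 fold changes. That prior count was not varied, and it matters most for genes near the floor. Depth limits genes under the floor of 0.076 to 0.106 CPM.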

Other observations

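One hypothesis was tested further, on lists chosen only after the pattern of ID genes and SERPINE1 was seen, with the predictions written before the test. ID genes are known targets of BMP signalling through SMAD1 and SMAD5, and SERPINE1 and COL1A1 of TGF-β signalling through SMAD2 and SMAD3. If ST101 moved cells from the first branch to the second, other targets of each branch, outside the fixed lists, would fall and rise. Of the TGF-β branch targets 12 of 14 rose and 1 fell in A549 (median 0.88; limma camera, unadjusted p-value 1.01e-21, and 0.0175 with an estimated correlation), and 12 of 13 rose and 1 fell in U251 (median 1.40; 1.71e-24, and 0.00522 with an estimated correlation). In MCF7 none of 12 was called (median -0.03; limma camera, unadjusted p-value 0.408). Of the BMP branch targets 1 rose and 1 fell of 10 in A549 (limma camera, unadjusted p-value 0.838), 1 fell of 10 in MCF7 (0.0592), and 4 rose and 2 fell of 9 in U251 (0.0765, with a positive test direction and a median of -0.06). The prediction on TGF-β targets was met in A549 and U251. In MCF7 it stays undecided, although the 4 ID genes fell there too. Other causes of the rise were not tested, so it does not show a move from one branch to the other. The part on BMP targets stays undecided in each line, since a p-value of 0.05 or more was set in advance to decide nothing.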
